A study of Mus musculus with 6 samples.

How the data were processed

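Single-cell RNA was measured in the aortic root of male mice aged 24 weeks. There were 3 genotypes: littermate controls, mice carrying a missense allele of Fbn1 on 1 chromosome (a mouse model of Marfan syndrome), and Marfan mice that also carried floxed Klf4. Per the labels, aortas of 4 animals per group were combined, digested with Liberase and elastase, and sorted for tdTomato, which marks cells of the traced smooth muscle cell (SMC) lineage. The lineage-positive and the lineage-negative fraction were each captured with the Chromium 3' version 3 chemistry, which gave 6 libraries, 1 per genotype and fraction. Each library was placed in its group from its title. Animals of a group cannot be told apart in the counts, so each group was a single sample.

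The deposited values were raw counts of unique molecular identifiers (UMIs) per gene and cell barcode. They were made with Cell Ranger, per the submitters' processing notes, and the matrices name version 6.1.2, per the file headers. The genome build was mm10, per the submitters' processing notes. The annotation release and the settings that called barcodes are not given in the sources used here. The gene list held 55402 features, of which 36715 had no UMI in any library, and 1 added feature, TDT, whose symbol matches the lineage reporter. Of the feature identifiers, 55141 were found in the GENCODE M21 annotation of the same build, 54349 of them with the same version number. Protein-coding genes held 99.9% of UMIs. Of 33505 features of other types, 71 had a UMI, so no statement is made on non-coding RNA. The markers Ighm, Igkc and Trbc2 were listed at 0 and could not mark B or T cells.

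Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from genes whose symbols begin with mt-. Doublets were scored per library with the Scrublet function of scanpy 1.11.5 and removed. Its automatic threshold marked 69 cells in the Marfan lineage-negative library and 70 in the lineage-negative library labelled Klf4-floxed. In the other libraries it marked under 0.5% of cells, and the top 0.8% of scores per 1000 cells were removed instead, as fixed beforehand. That removed 1171 cells of the Marfan lineage-positive library, 322 of the lineage-positive library labelled Klf4-floxed, 236 of the control lineage-positive library and 163 of the control lineage-negative one. The 39728 cells kept were scaled to 10000 UMIs, log-transformed and clustered without batch integration, on 2000 variable genes, 30 principal components and 15 neighbours, by the Leiden method (leidenalg 0.10.2) at resolution 1. Of 29 clusters, 23 were named from 19 marker sets written before the data were examined, which gave 10 classes. A cluster stayed unnamed when fewer than 3 of a class's markers were detected in at least 10% of its cells, when it held under 20 cells, when its leading 10 genes held more markers of another class than of its own or at least 2 of each, or when it matched modulated SMC and came mostly from lineage-negative libraries. These conditions were set after the data were examined. Clusters 8 and 14, whose best match was SMC, were unnamed because Tnnt2 or Rgs5, markers of cardiomyocytes and pericytes, stood among their leading genes. They held 5.22% and 1.25% of cells in the control lineage-positive library, 3.91% and 1.67% in Marfan, and 10.4% and 2.52% in the one labelled Klf4-floxed.

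Raw counts were summed per library and class. The SMC class comprised the lineage-positive cells of 4 clusters named SMC-like and 2 named modulated SMC-like. The fibroblast, endothelial and macrophage or monocyte classes were taken from the lineage-negative libraries. Levels are given as CPM, scaled to all UMIs of the class, with exact Poisson 95% intervals, ratios of CPM with exact conditional binomial 95% intervals, and shares with exact Clopper-Pearson 95% intervals. All cover counting error only. A group was 1 library, so no test was run and no p-value is given, no difference has a replicate check, and every ratio compares libraries, not conditions. Higher and lower describe these libraries. No value here pairs libraries across groups.

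Genes named in the text were chosen by a rule of size. For each SMC comparison these were the 10 largest and 10 smallest CPM ratios among genes with at least 20 CPM in the higher library and a UMI in at least 10% of its class cells, leaving out mitochondrial, ribosomal, haemoglobin, immunoglobulin and unnamed genes and markers of classes other than SMC, modulated SMC and fibroblast. To these were added up to 4 members of each of 20 gene lists fixed before the data were examined, and 11 genes named in advance. The other classes used the 5 largest and 5 smallest by the same rule. A list was summarised by the median log2 ratio of its members with at least 5 CPM in either library, and its order-statistic 95% interval. Also given were its members at least 1.5-fold higher or lower, and the percentile of its median among 10000 random lists of the same size. The random lists were matched on each member's CPM in the higher library. Percentiles describe these libraries. Some genes that the rule chose are not reported here.

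To compare cells across depths, each SMC class cell was thinned to 2000 UMIs, and shallower cells were left out. The share of a cell's UMIs from the modulated SMC and collagen lists was set against the 95th percentile of the control library. The ratios of both Marfan libraries to the control library share that control, so the correlation across genes was compared with 100 Poisson draws of unchanged groups. The interval step was tested on simulated Poisson counts in which random genes were changed by known folds. Such counts hold counting error only, as the intervals assume. They check the calculation, not whether intervals cover spread between cells, animals or libraries. In the simulated SMC comparison of Marfan against control, over 9231 genes, the interval lay on the right side of 0 for 100% of the genes changed 1.5-fold, and 95.2% of intervals held the true value. In the simulated endothelial comparison of Marfan against control, over 10362 genes, the interval lay on the right side of 0 for 43.5% of the genes changed 1.5-fold and 96.7% of those changed 4-fold.

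Alternatives listed before the data were examined changed the minimum to 500 or 2000 UMIs, the mitochondrial limit to 5% or 20%, the resolution to 0.5 or 2, the scaling (median of ratios, or totals without mitochondrial and ribosomal genes), the weighting of cells, the CPM minimum, the thinning depth, the removal of doublets, the SMC class (every lineage-positive cell), or clustered the sort fractions apart. Alternatives added after seeing the data used a minimum of 4000 UMIs, class cells of at least 4000 UMIs, the SMC class without its shallowest cluster, the SMC class with the unnamed SMC-type clusters, and modulation scored without Mgp. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3 and matplotlib 3.10.9 were used.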

Results

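The data comprised 6 single-cell libraries of the aortic root of male mice aged 24 weeks, with 3 genotypes and 2 sorted fractions each. Libraries were made from littermate controls, from Marfan mice (a missense allele of Fbn1, the fibrillin-1 gene, on 1 chromosome), and from Marfan mice labelled Klf4-floxed. Cells of the traced smooth muscle cell (SMC) lineage and lineage-negative cells were captured apart. There was 1 library per group, made from pooled animals, so no value below has a replicate error. The lineage-positive libraries held 8218 barcodes and 71583972 UMIs in control, 22905 and 87881816 in Marfan, and 8943 and 95250397 in the library labelled Klf4-floxed. The lineage-negative libraries held 5167 barcodes and 47750360 UMIs, 7879 and 81181913, and 7088 and 70598538, in the same order. In the Marfan lineage-positive library 39.0% of barcodes had fewer than 1000 UMIs, against 7.01% in control, and the cells kept had a median of 2153 UMIs, against 11379.5 in control and 12878 in the library labelled Klf4-floxed. Medians of the lineage-negative libraries lay between 9881 and 10337.

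The sort was checked with the reporter transcript TDT, which reached 340 CPM in the lineage-positive and 5.36 CPM in the lineage-negative control library. In Marfan these levels were 414 and 5.06 CPM, and in the pair labelled Klf4-floxed 226 and 2.75 CPM. Myh11, the smooth muscle myosin heavy chain, was 54.6-fold, 39.2-fold and 53.5-fold higher in the lineage-positive fraction of the 3 genotypes. SMC-like and modulated SMC-like clusters made up 91.8% [91.0, 92.5] of the control lineage-positive cells, 92.6% [92.1, 93.1] of Marfan and 84.6% [83.7, 85.5] of those labelled Klf4-floxed. These shares are set by the sort and by the naming of clusters: with a mitochondrial limit of 20% the control share was 45.7%, with the sort fractions clustered apart it was 13.2%, and with a minimum of 4000 UMIs per cell the Marfan share was 44.5%.

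To see which other cells the roots held, the lineage-negative libraries were compared by class. Macrophage- or monocyte-like cells made up 9.29% [8.45, 10.20] of control cells, 18.5% [17.6, 19.5] of Marfan and 14.3% [13.5, 15.2] of the library labelled Klf4-floxed. Fibroblast-like cells made up 72.1% [70.7, 73.4], 53.9% [52.7, 55.1] and 65.8% [64.6, 67.0]. Valve interstitial or chondrocyte-like cells, led by Chad, Comp and Cytl1, accounted for 9.55%, 8.44% and 7.41%, and endothelial-like cells for 2.88%, 3.14% and 3.78%. Neutrophil-like cells, marked by S100a8 and S100a9, accounted for 2.86% [2.48, 3.27] of Marfan cells, 0.161% of control and 0.0323% of the library labelled Klf4-floxed. Shares within a library sum to 100%, so one class being higher lowers the others. Summed erythroid markers, a sign of blood in the tissue, were 58.2 CPM in the Marfan lineage-negative library, 6.42 CPM in control and 5.52 CPM in the one labelled Klf4-floxed. With the sort fractions clustered apart, macrophage- or monocyte-like shares were 3.84%, 14.0% and 8.83%.

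**Figure D1:**
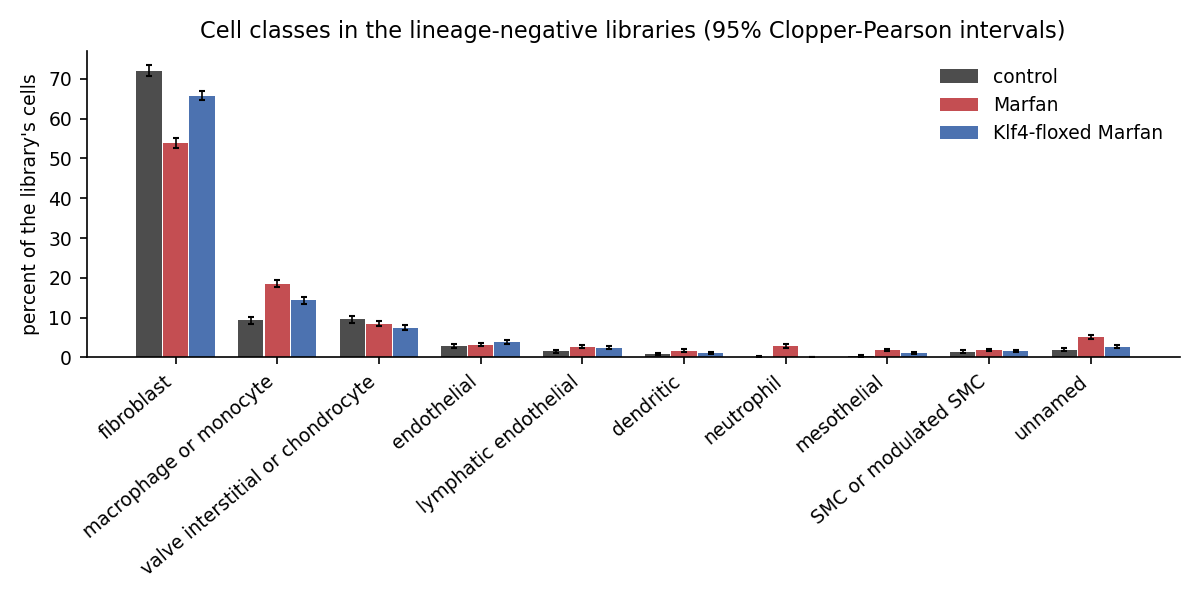
Percent of each lineage-negative library's cells in each class (bars, 1 library per genotype) with 95% Clopper-Pearson intervals for counting error. Fibroblast-like cells made up 72.1% of control, 53.9% of Marfan and 65.8% of cells in the library labelled Klf4-floxed, and macrophage- or monocyte-like cells 9.29%, 18.5% and 14.3%.

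Klf4, the zinc-finger factor that the study targeted, was read first. Klf4 (ENSMUSG00000003032.8) lies on the minus strand of chromosome 4 at 55527143 to 55532466 in mm10, with 5 exons. Over whole libraries it stood at 30.52 CPM in the control, 46.6 CPM in the Marfan and 120 CPM in the lineage-positive library labelled Klf4-floxed, and at 277, 267 and 359 CPM in the lineage-negative libraries. Within the SMC class it stood at 23.4 CPM [22.1, 24.7] in control, 39.9 [38.4, 41.5] in Marfan and 114 [111, 116] in the library labelled Klf4-floxed. The log2 ratio was 0.77 [0.67, 0.87] for Marfan against control and 1.51 [1.45, 1.58] for the library labelled Klf4-floxed against Marfan. Counts were thus not lower where the label says that Klf4 was floxed. The assay counts 3' ends, the labels do not name the floxed exons, and a 3' tag outside the deleted part checks nothing. Every comparison with this library therefore rests on its label. After thinning to 2000 UMIs, which left out 118, 5103 and 131 shallower cells, 3.72%, 6.78% and 16.8% of SMC class cells had a Klf4 UMI. Before thinning these shares were 15.8%, 13.6% and 51.9%, at median depths of 11551, 1975 and 13365 UMIs. No class here lacks Klf4. In the lineage-negative libraries, TDT was found in 1.26%, 0.554% and 0.115% of macrophage- or monocyte-like cells thinned to 2000 UMIs. Before thinning these shares were 3.47%, 2.91% and 1.35%, at median depths of 10540.5, 9659.5 and 8882.5 UMIs. The sort itself lowers TDT in those libraries. These shares thus do not measure free RNA in the lineage-positive libraries, where the SMC class was counted.

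The comparison of Marfan with control asks how SMC of the Marfan root differ from those of littermates. The class held 4768 control and 10120 Marfan cells, with 54367513 and 61381510 UMIs. Control cells came mostly from cluster 1 (60.4%) and cluster 11 (20.1%), and Marfan cells from cluster 0 (57.6% of cells at a median of 1358 UMIs, but 15.4% of UMIs), cluster 2 and cluster 1. Spp1, which encodes osteopontin, stood at 183 CPM in Marfan and 1.55 CPM in control, a log2 ratio of 6.88 [6.58, 7.21]. Under the alternatives that ratio lay between 5.93 and 8.89, outside the counting interval at both ends. Timp1, an inhibitor of metalloproteinases, stood at 293 and 29.4 CPM (3.32 [3.24, 3.39]), and Igfbp2, a binding protein of insulin-like growth factors, at 1209 and 142 CPM (3.09 [3.06, 3.12]). Fbln2 (3.42), Vcam1 (2.79), Thbs1 (2.39), Mmp3 (2.37), Tnfrsf11b (2.26) and Cd34 (2.16) were also among the 10 largest log2 ratios by the naming rule, which asked for a UMI in 10% of class cells and left out markers of some classes. Largest and lowest ratios refer to this rule throughout. Fetub (3.97) and Ttc9 (4.01) missed that share in the shallower Marfan cells, and were named for another comparison. The potassium channel gene Kcnj15 had the lowest ratio by that rule, with 17.9 CPM in Marfan and 72.5 CPM in control (-2.02 [-2.12, -1.93]). Krt18 (-1.85), Fibin (-1.71), Lrrc17 (-1.68), Psd (-1.53), Bmp3 (-1.53), Bmpr1b (-1.25), Angptl2 (-1.21), Aspn (-1.21) and Tnxb (-1.20) followed.

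All 15 genes of the modulated SMC list, a set of matrix and adhesion genes that SMC gain when they lose the contractile state, were at least 1.5-fold higher in Marfan. Their median log2 ratio was 2.15 [1.28, 3.32], or 4.43-fold, above every one of 10000 matched random lists. Fn1, or fibronectin, stood at 944 against 253 CPM (1.90), and Ly6a at 21.7 against 1.86 CPM (3.55). Of the list, 10 genes also served to name clusters, and Lum and Dcn are fibroblast markers as well. Beside this list, the summed fibroblast markers in the SMC class stood at 989 CPM in control and 1186 CPM in Marfan, the valve interstitial or chondrocyte markers at 244 and 274 CPM, the erythroid markers at 2.69 and 74.96 CPM, and the macrophage markers at 11.8 and 10.5 CPM. Of 16 proteases and inhibitors, 8 were at least 1.5-fold higher and none lower (median 0.51 [0.17, 1.78]), with Timp4 at 1.84, Mmp3 at 2.37 and Mmp2 at 1.78. Of 7 chondrogenic and osteogenic genes, 4 were higher (median 0.99 [-0.14, 2.53]), among them Cytl1 (2.53), Bmp4 (1.37) and Acan (1.33), which encodes aggrecan.

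The contractile apparatus list was near the median of all genes: none of its 23 genes differed by 1.5-fold, and its median log2 ratio was -0.08 [-0.24, 0.08] beside -0.08 over all genes. Myh11 stood at 2183 CPM in Marfan and 2692 in control (-0.30), Synpo2 at 322 and 467 CPM (-0.53), and Mustn1 at 970 and 733 CPM (0.40). Acta2 (0.18), Tagln (0.02) and Cnn1 (0.10) were slightly above 0. Their direction turned when doublets were kept (list median -0.37), with a minimum of 500 UMIs and with one of 4000 UMIs, and that of Tagln also with a mitochondrial limit of 5% and with mitochondrial and ribosomal genes left out of the total. That last scaling put the median of all genes at -0.13. Of 20 collagens and fibrillar matrix genes, 5 were higher and 1 lower (median 0.29 [-0.06, 0.56]), with Col15a1 at 0.65, Col1a1 at 0.63, P4ha1 at 0.60 and the proteoglycan gene Vcan at -0.65. Col3a1 (-0.06) was above 0 only under median-of-ratios scaling.

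Of 15 interferon response genes, 7 were higher and none lower (median 0.52 [0.28, 0.90]), with Isg15 at 1.002 and the class I antigen presentation genes H2-K1 at 0.82 and B2m at 0.64. Cluster 17 of the class, led by interferon-stimulated genes, held 0.767% of control and 2.40% of Marfan UMIs. Of 11 chemokine and inflammation genes, 6 were higher (median 0.69 [-0.16, 5.49]), among them the complement gene C3, at 24.8 against 0.552 CPM (5.49 [4.97, 6.06]), and Cebpd (0.69). In the unfolded protein response list, 4 of 16 genes were higher and none lower (median 0.39 [0.23, 0.68]), with Sdf2l1 at 1.58 and the chaperone Hspa5 at 0.69. Of 21 TGF-beta signalling genes, 4 were higher and 1 lower (median 0.07 [-0.09, 0.44]): Ltbp2 stood at 1.41, Tgfb1 at 0.88, Tgfb3 at 0.76 and the inhibitory Smad6 at -0.82. The elastic fibre list had 1 of 14 genes higher and 2 lower (median 0.17), with Loxl2 at 0.95 and Mfap4 at -0.90, while Fbn1, at 0.51 [0.46, 0.56], was under 1.5-fold. Of 4 genes on angiotensin and adrenergic receptors, 2 were higher (median 0.48), led by Ace, the angiotensin-converting enzyme, at 310 against 84.4 CPM (1.88). On the endothelial activation list 5 of 9 genes were higher (median 0.77), with Esm1 at 3.46, Klf2 at 0.83 and Vcam1. The SMC transcription factor list had 3 of 27 genes higher and 2 lower (median -0.09), with Heyl at -0.87 and Tead1 at 0.62. Notch had 1 of 10 higher and 2 lower (median 0.20), and the basement membrane list 1 of 11 higher (median 0.12), namely Nid1 at 1.35. Immediate early and heat shock genes had 2 of 20 higher and 1 lower (median 0.18), glycolysis and hypoxia 1 of 16 higher (median -0.02), and no gene differed by 1.5-fold among 16 of oxidative phosphorylation (median -0.16), 7 of lipid uptake and efflux (median 0.19) and 2 of the cell cycle (median -0.18).

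**Figure D2:**
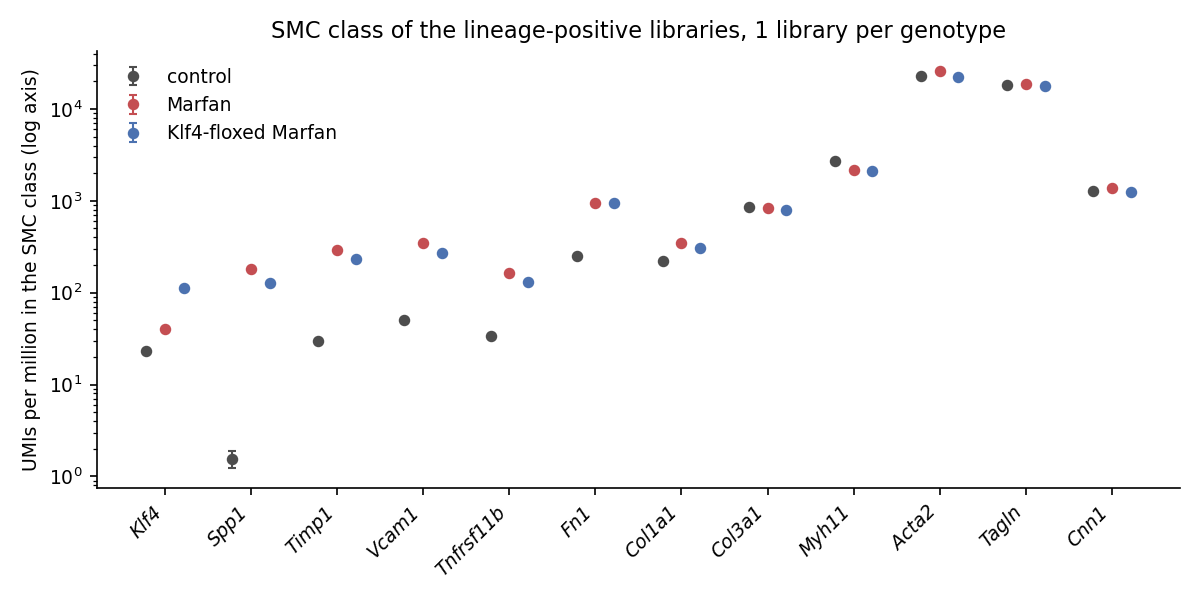
Level of 12 genes in the SMC class of the 3 lineage-positive libraries, in CPM on a log axis, with exact Poisson 95% intervals that are mostly narrower than the points. Spp1 stood at 1.55 CPM in control and 183 in Marfan, while Acta2, Tagln and Cnn1 lay close together, in an order that turned with the cell filters, and Klf4 was highest, at 114 CPM, in the library labelled Klf4-floxed.

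The library labelled Klf4-floxed was set against Marfan to ask how SMC of the Marfan root differ between these labels. Since Klf4 counts were higher under the label that names a floxed Klf4 allele, the values below are not given as effects of losing Klf4. Its SMC class held 5101 cells and 69567939 UMIs, mostly from cluster 2 (48.7%), cluster 5 (21.7%) and cluster 1 (20.7%). After Klf4, the largest log2 ratio by the naming rule was that of Dbp, a transcription factor under clock control, at 44.8 against 25.3 CPM (0.82 [0.74, 0.91]). Srpx2 (0.77), Atf3 (0.69), Gfra2 (0.66), Gldn (0.65), Nrgn (0.65), Ttc9 (0.60), Lrrc17 (0.56) and Tcap (0.56) followed. Ifi27l2a, an interferon-stimulated gene, had the lowest ratio by that rule, at 19.4 against 71.99 CPM (-1.89 [-1.98, -1.80]), and stood at 79.6 CPM in control. Pcolce2, which enhances procollagen processing, came next (-0.96), then Slc39a1 (-0.93), the metallothionein genes Mt2 (-0.89) and Mt1 (-0.73), TDT (-0.88), Cebpd (-0.87), the matrix proteoglycan gene Dcn (-0.79), Abhd2 (-0.75) and Lgals3 (-0.74). Without the shallowest cluster, Slc39a1 stood at -0.39 and Abhd2 at -0.31.

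Among the 15 modulated SMC genes, 4 were at least 1.5-fold lower than in Marfan and none higher, and the median log2 ratio was -0.34 [-0.63, -0.07], below every one of the 10000 random lists. Ly6a, at 1.18 against 21.7 CPM (-4.20 [-4.54, -3.88]), Dcn, Lgals3 and Lum (-0.63) were the lowest, while Fn1 stood at -0.01 [-0.03, 0.00]. Beside these, the summed fibroblast markers in the SMC class stood at 958 CPM, against 1186 in Marfan, the valve interstitial or chondrocyte markers at 181 against 274 CPM, the macrophage markers at 2.89 against 10.5 CPM, and the erythroid markers at 30.4 against 74.96 CPM. The sum of 10 modulated SMC markers, all on the list, went the other way, at 46135 against 40409 CPM. Most of it was Mgp, a gene chosen after its values were seen, at 44080 against 38060 CPM (0.21). Modulated SMC-like clusters held 19.2% of lineage-positive cells, against 10.0% in Marfan, where the shallow cluster 0 adds to the cells counted, and 1.87% in control. By UMIs of the SMC class, these clusters stood closer: cluster 5 held 25.1% against 20.7% in Marfan, and cluster 17 held 1.17% against 2.40%. Chemokine and inflammation genes had 5 of 11 members lower and none higher (median -0.56 [-3.69, -0.21]), led by C3 at 4.64 against 24.8 CPM (-2.42). Interferon response genes had 3 of 15 lower (median -0.29 [-0.57, -0.15]), among them Ifi27l2a and Isg15 (-0.73), while Bst2, at -0.57, was just short of 1.5-fold. The unfolded protein response list had none of 16 (median -0.17 [-0.25, -0.13]). Of 7 chondrogenic and osteogenic genes, 2 were lower (median -0.16 [-1.24, 0.04]), namely Comp (-1.24) and Cytl1 (-0.83), which are also lead genes of the valve interstitial or chondrocyte-like cluster.

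No gene differed by 1.5-fold between these libraries among 23 of the contractile apparatus (median -0.07 [-0.16, -0.04]), 20 collagens and fibrillar matrix genes (0.05 [-0.06, 0.12]), 21 of TGF-beta signalling (0.05), 16 of oxidative phosphorylation (0.01), 16 of glycolysis and hypoxia (-0.01), 11 of the basement membrane (-0.06), 7 of lipid uptake and efflux (0.07), 4 on receptors (0.02) and 2 of the cell cycle (0.10). The contractile median turned to 0.01 when each cell counted alike, as did Myh11, at -0.04, to 0.05 and Col3a1, at -0.06, to 0.01. Acta2 stood at -0.23, Tagln at -0.06, Cnn1 at -0.14, Des, which encodes desmin, at -0.56, and Col1a1 at -0.18. On the immediate early and heat shock list 2 of 20 genes were higher and 1 lower (median 0.05 [-0.10, 0.29]). Atf3 was one of the higher, while Hspa1a (0.48) and Fos (0.44) were under 1.5-fold. Among SMC transcription factors Klf4 alone of 26 genes passed 1.5-fold (median -0.02), as it did among 9 endothelial activation genes (median -0.11), and Id1 stood at -0.41 and Heyl at 0.48. Elastic fibre (median 0.00), protease (median -0.01) and Notch genes (median -0.04) had 1 lower member each, of 14, 16 and 9.

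Against control, SMC of the library labelled Klf4-floxed had 11 of 14 measured modulated SMC genes at least 1.5-fold higher and none lower, with a median log2 ratio of 1.92 [0.54, 2.98]. Spp1 stood at 128 against 1.55 CPM (6.37 [6.06, 6.70]), Fbln2 at 3.02, Timp1 at 2.98, Vcam1 at 2.45 and Tnfrsf11b at 1.96. Among the largest ratios by the naming rule were those of Gfra2, a receptor subunit for neurturin, at 21.5 against 0.754 CPM (4.83 [4.39, 5.32]), Ttc9 (4.61), Fetub (4.42), the cyclin gene Ccnd1 (3.42), Igfbp2 (3.07), Gdf10 (3.02), Fbln2, Timp1 and Gas7 (2.71). Under the alternatives, Gfra2 lay between 3.86 and 6.28, Fetub between 3.76 and 6.37, and Ccnd1 between 2.62 and 4.65, outside the counting intervals at both ends. Ifi27l2a (-2.03), Kcnj15 (-1.83), Pcolce2 (-1.78), Krt18 (-1.57), Bmp3 (-1.55), Psd (-1.49), Fibin (-1.48), Adm (-1.43), Enpp2 (-1.27) and Tnxb (-1.22) had the lowest. Of 23 contractile genes 1 was lower, Des (-0.83), and the median was -0.19 [-0.27, -0.05] beside -0.07 over all genes. Acta2 (-0.05), Tagln (-0.04) and Cnn1 (-0.04) stood above 0 under median-of-ratios scaling. Proteases and inhibitors had 7 of 16 genes higher (median 0.49 [0.15, 1.78]), collagens 4 of 20 (median 0.38 [-0.11, 0.52]), TGF-beta signalling 5 of 21 with 1 lower (median 0.10), and the interferon response 2 of 15 higher and 2 lower (median 0.19 [-0.07, 0.40]).

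**Figure D3:**
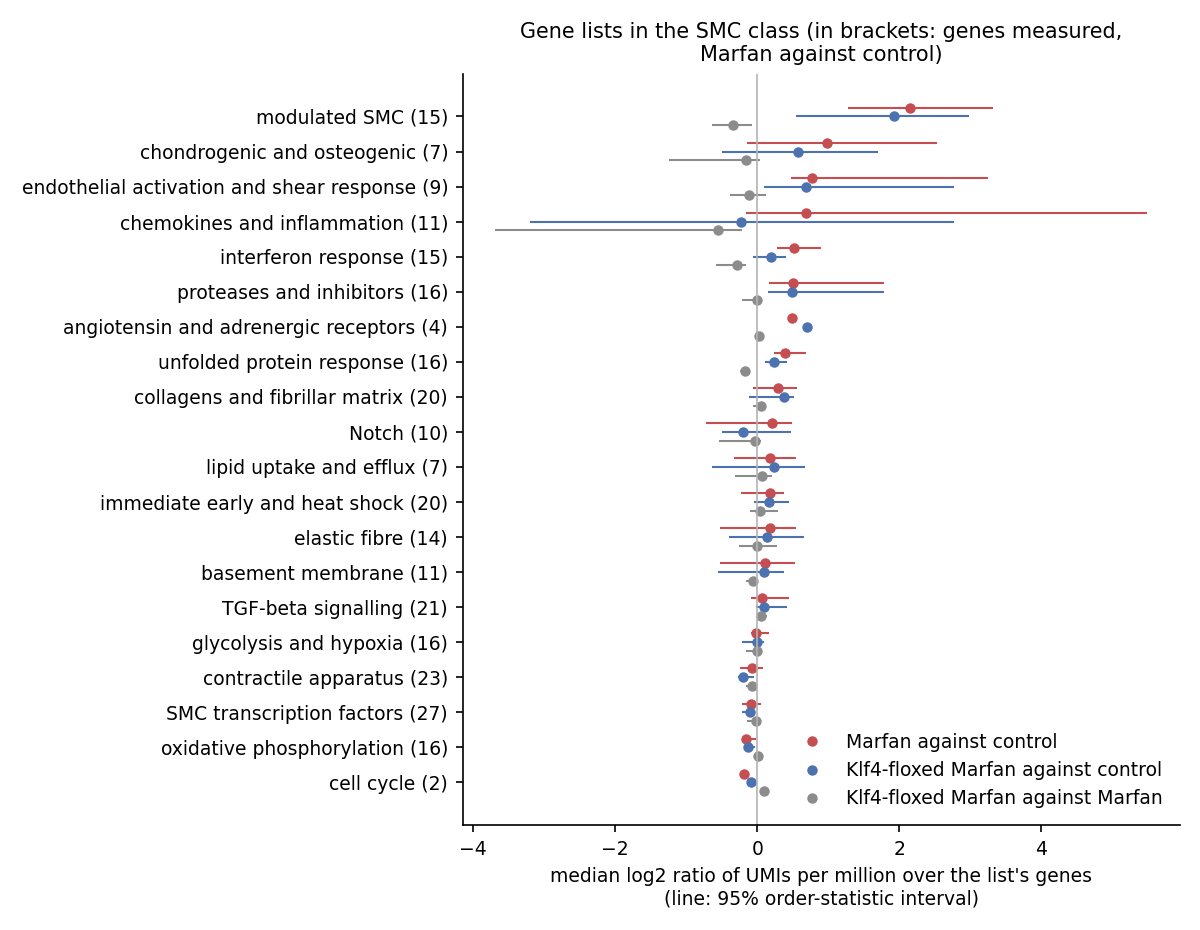
Median log2 ratio of CPM over the members of each gene list in the SMC class (points) with its 95% order-statistic interval where the list is long enough (lines), for the 3 comparisons. Modulated SMC genes had medians of 2.15 for Marfan and 1.92 for the library labelled Klf4-floxed, both against control, and -0.34 between the 2 libraries.

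Per cell, modulation was described by the share of UMIs from the modulated SMC and collagen lists after thinning to 2000 UMIs. Its median was 1.70% in 4650 control cells, 2.95% in 5017 Marfan cells and 2.88% in 4970 cells of the library labelled Klf4-floxed. Mgp alone stood at 13123, 38060 and 44080 CPM in the class, and without it the medians were 0.80%, 1.10% and 1.10%. Before thinning, over all class cells, with Mgp, the medians were 1.69%, 3.87% and 2.82%. The control library's 95th percentile was 4.83% of UMIs, and above it lay 30.7% [29.4, 32.0] of Marfan cells and 30.8% [29.5, 32.1] of cells labelled Klf4-floxed, against 5.01% of control cells by construction. Without Mgp, a limit of 1.45% left 24.5% and 24.6% above it. Cells above this limit are a range, not a type: 347 Marfan cells and 296 cells labelled Klf4-floxed lay within 10% of it. The median share of UMIs from contractile genes was 4.70% above and 8.90% below the limit in Marfan, and 3.50% and 8.25% in the library labelled Klf4-floxed. Control cells also differed, at 4.85% above and 7.40% below, so a lower share above the limit is not particular to the Marfan libraries. At the other settings the share above the limit was 23.0% to 48.5% in Marfan and 24.6% to 45.7% in the library labelled Klf4-floxed. Thinning left out 5103 of the 10120 Marfan cells as too shallow, so the Marfan share describes the deeper part of that library.

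**Figure D4:**
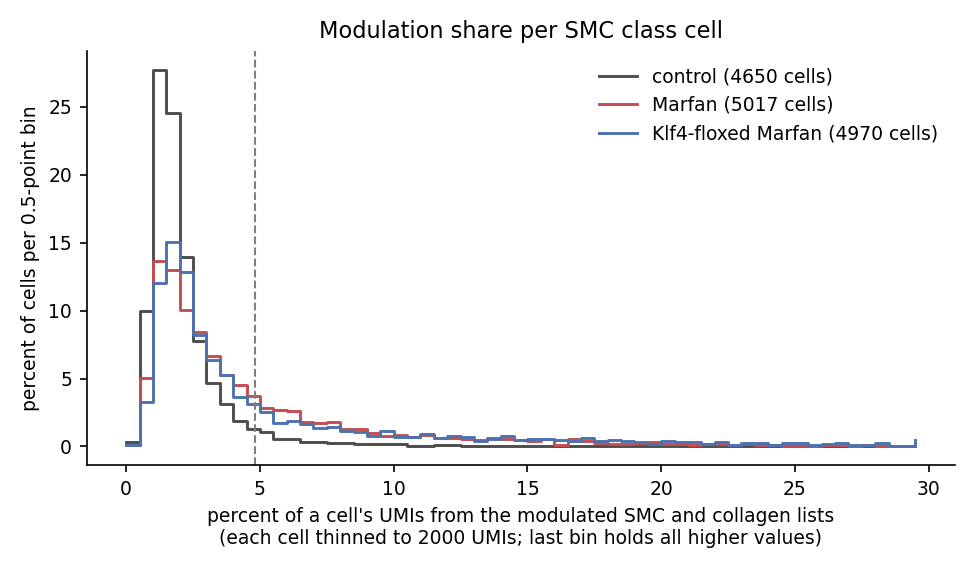
Distribution over SMC class cells of the percent of UMIs from the modulated SMC and collagen lists, each cell thinned to 2000 UMIs, as percent of the library's cells per bin. The dashed line is the control library's 95th percentile, 4.83%, above which lay 30.7% of Marfan cells and 30.8% of cells labelled Klf4-floxed.

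How far the Marfan libraries departed from control in the same genes was compared across 9432 genes of the SMC class. The log2 ratios of Marfan and of the library labelled Klf4-floxed, both against control, had a Pearson r of 0.898 and a Spearman rho of 0.815 across genes, which are not independent replicates. Both ratios use the same control library. Poisson draws of unchanged libraries, control included, gave a mean r of 0.546 and rho of 0.505. The covariance was 0.176, against 0.00233 in the simulation, a difference of 0.173. At least 2-fold higher than control were 187 genes in Marfan and 171 in the library labelled Klf4-floxed, with 150 in both where independent lists would share 3.39. At least 2-fold lower were 68 and 62 genes, with 38 in both and 0.447 for independent lists. The Poisson draws gave 0 genes in both, either way, and 0 in each library on its own. They hold counting error only, which does not reach 2-fold at this depth. They thus do not measure differences between separately made libraries or animals. Part of each excess can come from the shared control library, which could not be split.

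**Figure D5:**
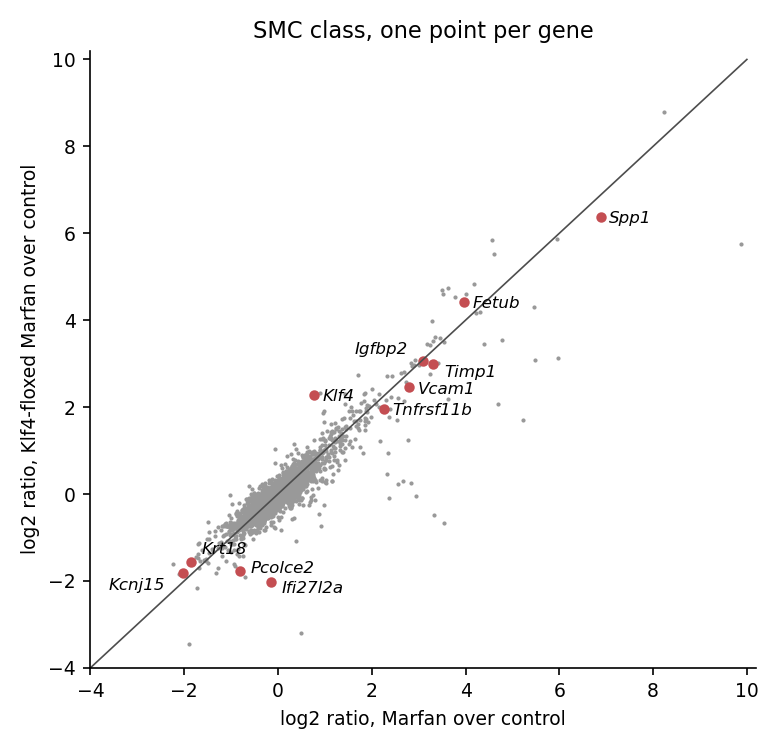
Log2 ratio of each of 9432 genes in the SMC class for the library labelled Klf4-floxed over control (vertical) against Marfan over control (horizontal), 1 point per gene, with the line of equal ratios. Spp1, Igfbp2 and Timp1 lie near the line, Klf4 above it (2.28 against 0.77) and Ifi27l2a below it (-2.03 against -0.14).

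In fibroblast-like cells, 3133 of control, 3793 of Marfan and 4073 of the library labelled Klf4-floxed, the chemokine and inflammation list was higher in Marfan than in control in 7 of 17 genes and lower in none (median log2 ratio 0.43 [0.04, 1.05]). Plac8 stood at 54.7 against 11.6 CPM (2.24 [2.08, 2.40]), Il6 at 23.5 against 7.50 CPM (1.64) and the LIM protein gene Fhl2 at 97.4 against 32.3 CPM (1.59), with Ifi205 at 1.64 and Serpini1 at 1.58. Il6 also stood at 3411 CPM in cluster 18 of the Marfan library and at 22.5 CPM [11.6, 39.3] in its neutrophil-like cells. In the same library it stood at 82.7 CPM in cluster 14, 15.2 in dendritic-like cells, 8.99 in cluster 8 and 0 in cluster 26. The part of free RNA in the fibroblast value was not measured. Hhip, an inhibitor of hedgehog signalling, stood at 9.04 against 34.6 CPM (-1.94), followed by Ifit2 (-1.50), Pex5l (-1.50), Ptgfr (-1.34) and Angptl7 (-1.23). Of 22 collagens and fibrillar matrix genes 1 was higher (median 0.16 [0.09, 0.29]), and of 15 modulated SMC genes 6 were higher and 1 lower (median 0.42 [-0.03, 0.94]), with Spp1 at 212 against 23.4 CPM (3.18). In the library labelled Klf4-floxed, chemokine and inflammation genes were lower than in Marfan in 6 of 17 and higher in 1 (median -0.20 [-0.94, -0.02]). Plac8 (-2.55), Ly6c1 (-1.80), Ifi205 (-1.71), Ccl2 (-1.60) and Ccl7 (-1.27) were lowest, and Rnf19b (1.67), Nr4a2 (1.25), Dbp (1.25) and Bdnf (1.15) among the highest. Interferon response genes had 2 of 17 higher and none lower (median 0.28 [0.02, 0.43]), and the collagen list 1 of 22 (median 0.01 [-0.13, 0.14]). The class was not made up alike: cluster 6, led by Pi16, Clec3b and Ly6c1, with C3 among its top genes, held 545 of these cells in control, 1058 in Marfan and 543 in the library labelled Klf4-floxed, and cluster 13, led by Cxcl10 and Ifit3b, held 171, 123 and 334. Ratios of the class were not separated from these shifts.

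Macrophage- or monocyte-like cells numbered 404, 1304 and 888 in control, Marfan and the library labelled Klf4-floxed. Cluster 12, led by Folr2 and Lyve1, held 222 of them in control, 304 in Marfan and 324 in the library labelled Klf4-floxed, cluster 9, led by Cd72 and Ccl4, held 155, 714 and 503, and cluster 19, led by Ly6c2 and Arg1, held 1, 218 and 15. Ratios and list medians of the macrophage class were not separated from these shifts. In Marfan, glycolysis and hypoxia genes were higher than in control in 7 of 16 and lower in none (median 0.42 [-0.18, 0.88]), with the growth factor gene Vegfa at 41.4 against 2.78 CPM (3.90 [3.11, 4.82]), and interferon response genes in 4 of 17 with 1 lower (median 0.36 [0.18, 0.52]). Spp1 stood at 503 against 36.5 CPM (3.78). Ly6c2 (7.34), Plac8 (6.98), Slfn4 (5.19) and Sirpb1c (3.78) had the other largest ratios, and Ly6c2 and Plac8 lead cluster 19 while Slfn4 leads the neutrophil-like cluster. The iron exporter gene Slc40a1 (-2.57), Slc9a3r2 (-2.61), Mmp9 (-2.28), Ildr2 (-2.27) and Lyz1 (-2.24) were lowest. In the library labelled Klf4-floxed, collagens and fibrillar matrix genes were higher than in Marfan in 11 of 18 and lower in 1 (median 0.70 [0.26, 0.86]), and glycolysis and hypoxia genes lower in 6 of 16 (median -0.48 [-0.71, -0.27]). Dcn, a fibroblast marker chosen after its values were seen, stood at 608 against 342 CPM in the same cells, and with a minimum of 500 UMIs that collagen median was 0.15. Slc40a1 (2.21), Ccl24 (1.60), Slc15a2 (1.43), Abi3bp (from 11.96 to 31.5 CPM) and Il1a (1.33) were highest against Marfan, and Slfn4 (-4.66), Ly6c2 (-3.92), Vegfa (-2.68), Plac8 (-2.61) and Sirpb1c (-2.58) lowest.

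Endothelial-like cells were few, 125, 221 and 234, with 1046023, 2059891 and 2023305 UMIs, so that ratios are wide. Cluster 23, led by Dkk2 and Wnt9b, held 69 of them in control, 34 in Marfan and 71 in the library labelled Klf4-floxed, and cluster 16, led by Pecam1 and Vwf, held 33, 141 and 130. The endothelial ratios below were not separated from these shifts, and Wnt9b, named below, is itself a lead gene of cluster 23. In Marfan, interferon response genes were lower than in control in 9 of 17 and higher in none (median -0.68 [-1.09, -0.20]), and chemokine and inflammation genes higher in 9 of 16 and lower in 2 (median 0.88 [0.06, 2.24]), with Cxcl1, a neutrophil attractant, at 45.1 against 2.87 CPM (3.98 [2.38, 6.28]). In the same Marfan library Cxcl1 stood at 4848 CPM in cluster 18, at 14.4 CPM in cluster 8 and at 134 CPM [83.8, 202] in cluster 26, and the part of free RNA in the endothelial value was not measured. Gdf6 stood at 50.5 CPM in Marfan, 0.956 in control and 2.97 in the library labelled Klf4-floxed, a log2 ratio of 5.72 [3.21, 11.04] for Marfan against control. Tmem252 (4.03) and the immune cell genes Tyrobp (3.95) and Bst1 (3.55) were the other largest, and Tspan32 (-6.11), the claudin gene Cldn11 (-4.17), Nova1 (-3.85), Gata5 (-3.79) and Smpd5 (-3.44) the lowest. Against Marfan, the library labelled Klf4-floxed had 10 of 16 chemokine and inflammation genes lower and none higher (median -0.68 [-1.07, 0.10]). Sfrp2, a modulator of Wnt signalling, stood at 33.1 against 225 CPM (-2.76 [-3.15, -2.39]), and Wnt9b (2.15), Rgs7bp (1.95), Tmem108 (1.92), Epha7 (1.89) and Lsamp (1.89) were highest. Of 21 collagens and fibrillar matrix genes 1 was higher and 1 lower (median -0.09 [-0.21, 0.20]).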

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

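Of the tests below, those on Klf4 counts, on the modulated SMC list and on a single animal of the pool were chosen only after the result was seen.

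Klf4 counts in the SMC class were higher in the library labelled Klf4-floxed than in Marfan (log2 ratio 1.51 [1.45, 1.58]). This stood out because the label names a floxed Klf4 allele, though not a deletion. An immediate early response to cell preparation, as a shift of the whole immediate early and heat shock list, is argued against by that list. Its median was 0.0458 [-0.10, 0.29] where that response would need at least 0.5 of Klf4's ratio. Klf4 also stood at 0.33 [0.30, 0.37] in fibroblasts, 0.41 [0.35, 0.48] in macrophages and 0.07 [-0.06, 0.21] in endothelial cells of the lineage-negative libraries. A smaller part from preparation, shared by both fractions, thus stays open. RNA from fibroblasts, endothelial cells or macrophages is argued against by the marker sums in the SMC class: fibroblast markers were lower in the library labelled Klf4-floxed than in Marfan (957.668 against 1186 CPM), as were endothelial (13.4 against 16.8) and macrophage markers (2.89 against 10.5). RNA from other types was not tested, and pericyte markers were higher (283 against 264). A transcript that keeps its 3' end after recombination, and cells that did not recombine, stay open, since counts per gene, with a Klf4 UMI in 16.7807% of thinned cells, hold no exon. A difference between genotypes stays open as well, untested with 1 library per group.

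The modulated SMC list was higher in the Marfan lineage-positive library than in control, with a median log2 ratio of 2.15 [1.28, 3.32]. For the low depth of that library, the median with class cells of at least 4000 UMIs was 2.12147 [1.28, 3.31]. Counts were summed, and the shallow cluster 0 held 57.6% of Marfan class cells but 15.4% of UMIs. This median could thus hardly fall, and shows only that shallow cells do not carry the sum. The list also stood at 1.92 [0.54, 2.98] in the library labelled Klf4-floxed, which had control-like depth. Such a rise thus did not need low depth, but depth was not tested further in the Marfan library. Macrophage RNA is argued against: a median of 304.77% [17.4, 922] of the class's RNA would be needed, and the macrophage markers allow 0.0370%. Fibroblast RNA stays open: a median of 45.3901% [2.04, 156] would be needed and the fibroblast markers allow 3.89%, which 11 members exceed while Ly6a, Lum, Dcn and Ptn need less. The genotype and a difference between library preparations cannot be told apart with 1 library per group.

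Neutrophil-like cells accounted for 2.86% of the Marfan lineage-negative library, above 0.161% in control, in a cell class that the comparisons did not use. The minimum of 1000 UMIs alone is argued against, since at 500 UMIs the share was 2.99325% [2.61, 3.42] in Marfan and 0.179% [0.0775, 0.353] in control. That test kept the minimum of 500 genes and added few cells (4461 in control, against 4347). Whether the cell filters together removed neutrophils from the other libraries stays open. More blood left in the Marfan tissue is a candidate explanation that passed its test: erythroid markers stood at 58.1595 CPM in that library, against 6.42 and 5.52 CPM in the other lineage-negative libraries. In the lineage-positive libraries they stood at 68.1 CPM in Marfan, 27.0 in the one labelled Klf4-floxed and 2.65 in control. The pool labelled Klf4-floxed thus also held erythroid RNA, while 0.0323% of its lineage-negative cells were neutrophil-like. Blood stays a candidate only. That 1 animal of the pool brought these cells (2.85674%) stays open, since animals carry no tag, and a difference between genotypes stays open untested.

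Other signals appeared above the control level in cells that no comparison used. Of the Marfan lineage-negative cells 1.69% were dendritic-like, marked by Cd209a, against 0.805% in control. Lymphatic endothelial-like cells, marked by Ccl21a, accounted for 2.66% in Marfan and 2.36% in the library labelled Klf4-floxed, against 1.54% in control, and mesothelial-like cells, marked by Upk3b and Msln, for 1.79% and 1.02%, against 0.345%. Cluster 18, unnamed, held 3.48% of Marfan lineage-negative cells and none of control or of the library labelled Klf4-floxed, at a median of 21834 UMIs. Its best marker match was modulated SMC, then fibroblast, with Dcn at 2875 CPM, Col1a1 at 1970 and Myh11 at 3.28 CPM. It carried Cxcl1 at 4848 CPM, Il6 at 3411, Il11 at 2738, Cxcl5 at 2466 and Csf3 at 730 CPM. Among lineage-positive cells of the library labelled Klf4-floxed, the unnamed SMC-type clusters 8, led by Tnnt2 and Gja4, and 14, led by Ifitm1 and Rgs5, held 10.4% and 2.52%, against 5.22% and 1.25% in control.

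Some gene lists had medians on opposite sides of 0 in different cell classes when scaled to totals, each with an interval that left out 0, and these differences were not tested. Against control, Marfan had medians for the interferon response of 0.52 in SMC and 0.36 in macrophages but -0.68 in endothelial cells, for oxidative phosphorylation of 0.072 in fibroblasts, 0.19 in endothelial cells and 0.13 in macrophages but -0.16 in SMC, and for immediate early and heat shock genes of 0.21 in fibroblasts but -0.30 in macrophages. Between the library labelled Klf4-floxed and Marfan, medians for chemokines and inflammation were 0.21 in macrophages but -0.56 in SMC and -0.20 in fibroblasts, for the interferon response 0.28 in fibroblasts but -0.29 in SMC and -0.36 in macrophages, and for immediate early and heat shock genes 0.16 in macrophages but -0.22 in endothelial cells. Between the library labelled Klf4-floxed and control, the contractile list stood at 0.28 in fibroblasts and -0.19 in SMC, and oxidative phosphorylation at 0.14 in endothelial cells and 0.090 in macrophages but -0.14 in SMC. For SMC, the oxidative phosphorylation and contractile intervals here hold the median over all genes (-0.08 for Marfan and -0.07 for the library labelled Klf4-floxed, both against control). For macrophages so do those of chemokines and of immediate early genes between the Marfan libraries (0.03). Whether these intervals leave out 0 can thus depend on the scaling. Shifts between the clusters that make up a class were not separated from these medians either. The SMC contractile median of the library labelled Klf4-floxed against control stayed between -0.51 and -0.12 over 17 alternatives.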

How the results depend on the processing

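Alternatives with a minimum of 4000 UMIs, with class cells of at least 4000 UMIs, without the shallowest SMC cluster, with the unnamed SMC-type clusters and with modulation scored without Mgp were chosen after the data were seen. Groups had 1 library each, so none could be left out. No paired analysis was possible because each group has a single library. Clustering the sort fractions apart was run for cell shares only. Over the 17 alternatives run for list medians, the median log2 ratio of the modulated SMC list stayed between 1.83 and 3.16 for Marfan against control, between 1.63 and 2.63 for the library labelled Klf4-floxed against control, and between -0.47 and -0.25 between these libraries, and that of collagens between 0.21 and 0.37, 0.22 and 0.45, and 0.01 and 0.11. Over 14 alternatives, Klf4 in the library labelled Klf4-floxed against Marfan stayed between 1.37 and 1.56. Under alternatives chosen beforehand, 230 values of the main results stayed within the 95% interval of the main value, 75 lay outside it and 1 turned. Under those added later, 57 stayed within and 20 lay outside. For list medians that interval is the order-statistic one over members, and for the correlation it is one over genes. Staying within these does not show agreement within counting error. A turn was counted only for ratios whose interval left out 0. For 83 results of named SMC genes, 1222 of 1245 values kept their direction and 23 did not, 588 stayed within the counting interval, and 70 moved by over 1.5-fold. Among these, for Marfan against control Spp1 reached 8.89, Thbs1 4.29, Fbln2 4.24, Vcam1 4.03, Timp1 4.02, Cd34 3.93, Mmp3 3.74 and Tnfrsf11b 3.16. For the library labelled Klf4-floxed against control Fetub reached 6.37, Gfra2 6.28, Ccnd1 4.65, Gdf10 4.06, Gas7 3.54 and Tnfrsf11b 2.81. Some ratios shrank instead. For Marfan against control Psd came to -0.90 and Spp1 to 5.93, and for the library labelled Klf4-floxed against control Psd came to -0.89 and Igfbp2 to 2.43. Between the Marfan libraries Slc39a1 lay between -1.92 and -0.30 and Abhd2 between -1.62 and -0.24. Depth limits the Marfan lineage-positive library, where thinning left out 5103 of 10120 SMC class cells. With a minimum of 500 UMIs the endothelial class fell under 50 cells in a library and gave no value.

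In what follows, contractile means the median log2 ratio of the contractile list in SMC, r the Pearson correlation across genes, modulation the share of cells above the control limit in Marfan and then in the library labelled Klf4-floxed, and SMC share the SMC-like and modulated SMC-like share of lineage-positive cells in control, Marfan and the library labelled Klf4-floxed. Except where given, the cause was not tested.

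With a minimum of 500 UMIs, for Marfan against control contractile was -0.30, Klf4 0.89, Acta2 -0.090, Tagln -0.12 and Cnn1 -0.19, for the library labelled Klf4-floxed against control contractile was -0.42 and Klf4 2.39, r was 0.910, modulation 40.05% and 38.5%, SMC share 67.8%, 78.1% and 48.4%, and the collagen median in macrophages 0.43 for Marfan against control and 0.15 for the library labelled Klf4-floxed against Marfan. With doublets kept, the same SMC values were -0.37, 0.91, -0.14, -0.12 and -0.26, then -0.51 and 2.46, r 0.926, modulation 48.5% and 45.7%, SMC share 56.2%, 73.0% and 43.2%, the macrophage share of Marfan 15.5%, and the endothelial collagen median -0.27 against Marfan. With a minimum of 4000 UMIs they were -0.33, 1.03, -0.14, -0.15 and -0.22, then -0.44 and 2.54, r 0.936, modulation 40.6% and 42.4%, SMC share 64.1%, 44.5% and 43.8%, and the macrophage share of Marfan 15.7%.

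With a mitochondrial limit of 5%, Klf4 was 0.89 and Tagln -0.020 for Marfan against control, contractile -0.32 and Klf4 2.39 for the library labelled Klf4-floxed against control, r 0.903, modulation 34.3% and 36.3%, and SMC share 52.1%, 82.6% and 59.4%. With a limit of 20%, r was 0.903, modulation 32.2% and 33.2%, SMC share 45.7%, 78.8% and 58.8%, the macrophage share of Marfan 15.2%, and the endothelial collagen median -0.56 for the library labelled Klf4-floxed against control. With a minimum of 2000 UMIs, Klf4 was 2.40 for the library labelled Klf4-floxed against control, r 0.884, Marfan modulation 28.2%, and SMC share 81.0%, 54.5% and 62.0%. At resolution 0.5, r was 0.903, Marfan modulation 29.3%, SMC share 57.2%, 87.0% and 74.7%, and the macrophage share of Marfan 15.2%. At resolution 2, modulation was 24.7% and 28.3% and SMC share 86.0%, 80.0% and 79.0%. With the sort fractions clustered apart, SMC share was 13.2%, 82.2% and 60.8%, and the macrophage share 3.84%, 14.0% and 8.83%.

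With every lineage-positive cell as SMC, Klf4 was 0.61 for Marfan against control, 1.37 for the library labelled Klf4-floxed against Marfan and 1.98 against control, r 0.860, and modulation 23.0% and 24.6%. With the unnamed SMC-type clusters added, Klf4 was 1.43 against Marfan and 2.18 against control, and modulation 24.4% and 26.4%. Without the shallowest cluster, r was 0.871 and Marfan modulation 29.3%, and with class cells of at least 4000 UMIs the latter was 27.8%. Thinned to 1000 and to 4000 UMIs, it was 33.9% and 28.1%. Without Mgp, modulation was 24.5% and 24.6%. With a UMI in both libraries, r was 0.759, and at a CPM of at least 50 it was 0.925, both over another set of genes by construction.

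Scaling moved genes close to 0 across it. With totals without mitochondrial and ribosomal genes, Tagln was -0.028 for Marfan against control. Under median-of-ratios scaling, Col3a1 was 0.014 for Marfan against control, and Acta2 0.023, Tagln 0.027 and Cnn1 0.035 for the library labelled Klf4-floxed against control. With the mean over cells, contractile was 0.0080, Myh11 0.051 and Col3a1 0.0098 for the library labelled Klf4-floxed against Marfan, Cnn1 0.0060 for it against control, and r 0.830.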

Other observations

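The test on harvest time below was written before the values it measures were seen. Fibroblast-like cells of the library labelled Klf4-floxed also stood apart from control in genes of the stress response. On the immediate early and heat shock list 8 of 20 genes were at least 1.5-fold higher and none lower (median log2 ratio 0.45 [0.21, 0.78]), with the nuclear receptor gene Nr4a1 at 329 against 170 CPM (0.95 [0.90, 0.99]). Of 19 contractile genes 3 were higher and none lower (median 0.28 [0.03, 0.50]), while Acta2, at 342 against 242 CPM (0.50), was under 1.5-fold. Serpini1 (2.10), Lmo7 (1.80), Cthrc1 (1.75), Fhl2 (1.69) and the neurotrophin gene Bdnf (1.63) had the largest ratios, and the prostaglandin receptor gene Ptgfr (-1.69), Ccnb1ip1 (-1.55), Angptl7 (-1.45), Hhip (-1.39) and the transcription factor gene Foxd1 (-1.33) the lowest.

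In macrophage- or monocyte-like cells of the library labelled Klf4-floxed, 11 of 18 collagens and fibrillar matrix genes were higher than in control and none lower (median 0.64 [0.39, 0.84]), with Postn, which encodes periostin, at 65.4 against 24.997 CPM (1.39) and Col1a1 at 62.4 against 28.0 CPM (1.16), beside the fibroblast marker Dcn at 608 against 428 CPM. Serpina3n (2.31), Dkk3 (1.61), the growth factor gene Areg (1.52) and Tm4sf1 (1.44) had the other largest ratios. The chemokine gene Cxcl13, at 187 against 807 CPM (-2.11 [-2.20, -2.03]), the water channel gene Aqp1 (-2.01) and the endothelin receptor gene Ednrb (-1.85) were lowest.

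Dbp, a gene under clock control, was among the largest ratios of the library labelled Klf4-floxed over Marfan in SMC (0.82) and fibroblasts (1.25). A hypothesis is that the tissues may have been taken at different times of day. In fibroblasts, evening-phase clock genes without Dbp had a median log2 ratio of 0.38 and morning-phase genes of -0.28. Per2 alone of these evening-phase genes was lower (-0.62 [-0.89, -0.35]), while the others were higher, from Hlf (0.13) to Nr1d1 (0.88). The medians had a difference of 0.657401 where at least 0.5 had been set for harvest time. The difference was 0.57 in SMC, 0.84 in endothelial cells and 0.51 in macrophages, where the morning-phase median was not lower (0.094). It was not particular to the library labelled Klf4-floxed: for Marfan against control it was -0.57 in fibroblasts, -0.75 in endothelial cells and -0.14 in macrophages but 0.19 in SMC, and for the library labelled Klf4-floxed against control 0.089, -0.33, 0.31 and 0.58 in the same order. Against control the classes thus differed in sign, and harvest time stays open. The labels give no harvest times, and an effect of genotype on the clock was not tested.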
